A study of Mus musculus with 112 samples.

How the data were processed

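Messenger RNA levels were measured in whole lung tissue of mice on Illumina MouseRef-8 v2.0 bead arrays, a platform that reads each transcript with 1 or more short probes. Per the labels and the series design text, mice were kept in constant light (noted as LL 12:12), 40 of them were injected into the peritoneum with 12 mg/kg of lipopolysaccharide (LPS, endotoxin of E. coli O127:B8) late in the subjective day, and collection every 4 h began directly afterwards. The interval between injection and collection at 0 h is not given. Groups were taken from the treatment and the collection time in the labels. This gave 12 LPS groups (0 to 44 h, 40 animals) and 19 untreated groups (0 to 72 h, 56 animals). The 2 animals that had 2 arrays each were averaged on the log2 scale and counted once. The 14 arrays of control RNA carry no treatment or time and entered no comparison.

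The deposited values are on a log2 scale, which was read from their range of -3.41 to 17.40, and the authors' transformation, background correction and normalization are not given in the sources used here. The array means lie between 5.69 and 5.78 while the array medians lie between 4.53 and 5.43, so the columns had not been brought to 1 common distribution. Per the labels, RNA was amplified and labelled in 1 run and samples were placed on 14 chips at random. No detection p per probe was used here, so dim probes were kept in the main analysis. Of the 25697 probes, 23978 carried 1 gene symbol in the platform annotation and 1719 carried none, and 23962 gene identifiers matched the mouse gene table used to update symbols. Where several probes read 1 of the 16593 genes, the probe with the highest mean over all labelled animals stands for the gene. No genome coordinates were used.

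Values were fitted per probe with limma 3.58.1 in R 4.3.3, with the data.table package (1.17.8) for handling, and the adjusted p-values in the text are limma's unless another test is named. The effect of LPS was the difference between LPS and untreated animals at the same collection time, in 1 model with a mean per group and 1 estimate of spread over all 96 animals. Moderated tests with a variance trend were adjusted by the Benjamini-Hochberg method over all probes at a threshold of 0.05. The effects at 4, 8 and 12 h and those at 24 to 44 h were also averaged with equal weights. Rhythms were fitted as a 24 h cosine and sine wave with a linear trend, in each arm alone, and the difference in the wave between arms was tested as an interaction over 0 to 44 h. A rhythm was called recurrent when the probe also had an unadjusted p under 0.05 and a peak within 4 h in a fit of 20 to 44 h only. The clock amplitude ratio and the clock period are a median and a best fit over a fixed list of clock genes, with errors from 1000 bootstrap draws of animals within groups and a permutation test of 100000 draws within collection times for the ratio.

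A set of 30 gene lists was tested with camera (preset inter-gene correlation 0.01) at 0 h, 4 to 12 h and 24 to 44 h, adjusted over 90 tests. They cover the clock and its outputs, cytokines and NF-kB targets, interferon response, acute phase, coagulation, glucocorticoid response, heat shock, endoplasmic reticulum (ER) stress, hypoxia, oxidative phosphorylation, cholesterol synthesis, xenobiotic metabolism, cell cycle, and markers of neutrophils, alveolar macrophages, monocytes with interstitial macrophages, dendritic cells, B cells, T and NK cells, alveolar type 1 and type 2 cells, club cells, ciliated cells, endothelium, fibroblasts and matrix, smooth muscle, heart muscle, fat and red cells. Some genes stand on more than 1 list. For 4 members without a probe, matching by synonym or by the alias fixed beforehand took the probe of another gene. These were Olfr48 for C3 (acute phase), Ly6c1 for Ly6c2 (monocyte), Spag6l for Spag6 (ciliated) and Eno1b for Eno1 (hypoxia). A setting added later left them out and called the same lists. The lists, the tests, the alternatives not said to be added later and the rule for named genes were fixed before the data were examined. That rule names the 10 largest rises and 10 largest falls at 0 h, 4 to 12 h and 24 to 44 h with 1 sign at every time of the window, up to 4 members per list with the largest change, every clock gene, the 10 largest amplitudes per rhythm and the 10 smallest p for the rhythm difference. Other genes named were chosen after their values were seen, and the text says so. List scores are means over members per animal.

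The procedures were tested on simulated data over 25697 probes with 50 changed probes per size. At 0 h the test recovered 8%, 34%, 64% and 94% of probes changed by 0.5, 1, 2 and 3 log2 units, at 40 h 4%, 26%, 56% and 94%, and for the mean of 24 to 44 h 40%, 76%, 100% and 100%. For waves of amplitude 0.25, 0.5, 1 and 2 it recovered 38%, 70%, 98% and 100% in untreated animals over 0 to 72 h, and 12%, 44%, 94% and 98% in LPS animals over 0 to 44 h. Lists shifted by 0.3 were called in 7 of 9 tests and unshifted lists in 0 of 81, over 16593 genes. The simulated noise was independent between genes, so this run does not test list calls where genes move together. With treatment labels regrouped within collection times, camera still made a median of 20 list calls, so its p-values carry less weight than their size. A simulated clock amplitude ratio of -1.32 log2 came out at -1.17 over 22 genes.

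The alternatives were quantile normalization, subtraction of array medians, the chip as a block, only probes with a mean level above the median, no variance trend, a 2-fold threshold, only the 2 groups compared, other trends, periods, waveforms and windows, a peak tolerance of 2 h, estimated inter-gene correlation, fry, all probes per gene, and leaving out each animal. Settings without certain times, without arrays of low median, without the 4 exchanged list members, with the heart muscle score as a covariate, with other choices of clock genes, and with periods of 22 h and 27 h were added after the data had been seen. The number of animals per group limits the precision. The labels describe each sample as a separate mouse, so the spread between samples is that between animals. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.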

Results

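Whole-lung RNA was profiled in 96 mice, in order to compare daily rhythms of expression between healthy and endotoxaemic lungs. A single injection of LPS, a bacterial outer membrane component that triggers innate immune signalling, was given to 40 mice. The labels give 96 distinct animals whereas the design text names 94, and the labels were followed. The lighting is given as constant light but with a 12:12 notation, so it is not certain that the rhythms were free-running. LPS groups held 3 animals each, or 4 at 4, 12, 20 and 28 h, and untreated groups held 3 animals each, or 2 at 72 h. Values are the deposited log2 expression levels of 25697 probes, and the number of arrays limits their precision. Between animals of 1 group the median correlation over all probes was 0.971 and the lowest was 0.939. The 2 animals measured on 2 arrays gave correlations of 0.971 and 0.980 between their arrays. The median standard deviation between animals of a group was 0.597 log2 units over all probes and 0.292 over the brighter probes, those with a mean level above the median.

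Transcripts of cytokines, interferon targets and neutrophil products rose in the LPS lungs, and many endothelial and, later, B cell and ciliated cell genes fell. As lists these falls were called by camera at the preset correlation, and with an estimated correlation the calls were lost (adjusted p = 0.175 and 0.406 for endothelial at 4 to 12 h and 24 to 44 h, 0.406 for B cell and 0.435 for ciliated genes). They were kept with fry, which asks whether a list moves at all and not whether it moves more than other genes. Of 23 endothelial genes 4 rose in each window, and ciliated scores went with the heart muscle score. The number of probes that changed against untreated animals of the same time went from 139 at 0 h to 3264 at 4 h and 8475 at 8 h. It was 9333 at 12 h, 8784 at 16 h, 6764 at 20 h, 9625 at 24 h, 10725 at 28 h, 10343 at 32 h, 9425 at 36 h, 3835 at 40 h and 8206 at 44 h. At 4 h 2178 probes rose and 1086 fell, and at 28 h 5066 rose and 5659 fell. The chemokine Cxcl10 was higher by 10.33 log2 units (SE 0.95) at 36 h, by 4.16 (SE 0.95) at 40 h and by 6.95 (SE 0.95) at 44 h. The endothelial transcription factor Sox18 was lower at 36 h by a log2 change of -4.89 (SE 0.58), and at 40 h its change of -0.20 (SE 0.58) did not pass the test (adjusted p = 0.881).

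The animals at 4 h were divided, so the spread pooled over all groups may understate theirs. Their interferon list scores were 9.84, 8.41, 11.69 and 11.78 for replicates 1 to 4, and their neutrophil scores 8.56, 8.31, 10.76 and 10.81, against 8.35 and 7.70 as the highest untreated scores. On the cytokine list replicates 1 and 2 (6.91 and 6.46, others 11.15 and 11.29) lay within the range of untreated animals (5.86 to 6.96). The same held for the acute phase list (8.28 and 8.32, others 11.61 and 11.73, untreated 6.96 to 8.73). Without LPS replicate 3 or 4 the count at 4 h was 1332 or 1330, and without untreated replicate 1 it was 1978. At 0 h the count without LPS replicate 3 was 85, and at 40 h without LPS replicate 3 it was 2415. The split into rises and falls depended on the scaling between arrays. With array medians subtracted the share of rises went from 66.7% to 34.3% at 4 h, where it was 47.2% with quantile normalization. With array medians subtracted it went from 51.8% to 30.4% at 8 h, from 49.3% to 65.6% at 12 h, and from 48.1% to 61.8% at 16 h. It also went from 48.9% to 64.6% at 24 h, from 47.2% to 65.7% at 28 h, from 52.5% to 64.5% at 40 h and from 51.5% to 62.8% for the mean of 24 to 44 h. That setting moved the median change of all probes by between -0.37 (8 h) and 0.39 (28 h) log2 units.

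**Figure D1:**
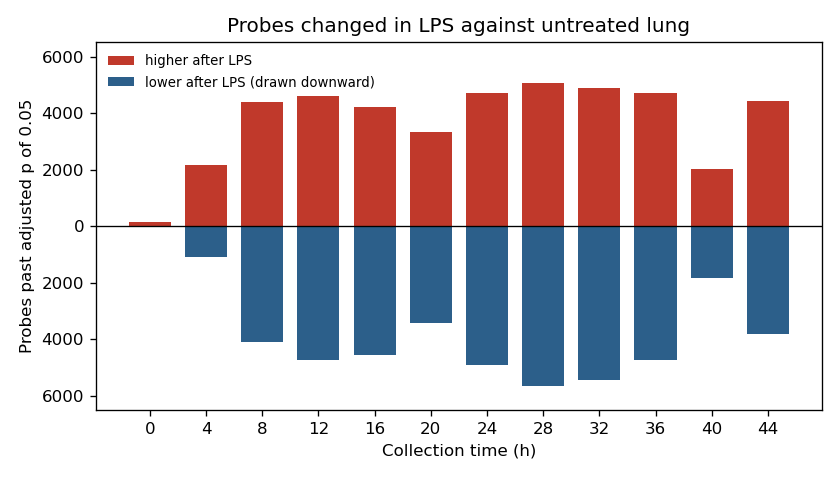
Number of probes that rose (above 0) or fell (below 0) in LPS against untreated lungs at each collection time in h, at an adjusted p under 0.05 in limma. The counts were 139 at 0 h, 10725 at 28 h and 3835 at 40 h, with 3 or 4 LPS animals and 3 untreated animals per time.

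Lungs of the 0 h group already carried high levels of early inflammatory transcripts. The cytokine Tnf was higher by 7.60 log2 units (SE 0.82, 3 LPS and 3 untreated animals, adjusted p = 1.54e-10) and Il1b by 6.18 (SE 0.48, adjusted p = 5.31e-16). The neutrophil chemokines Cxcl2 and Cxcl1 rose by 7.02 (SE 1.06) and 6.44 (SE 1.03), the endothelial adhesion molecule Sele by 5.55 (SE 0.91), and the immediate early transcription factors Egr4 and Atf3 by 4.86 (SE 0.65) and 4.79 (SE 0.53). The remaining members of the 10 largest rises were Clec4e (5.50, SE 0.73), Cxcr2 (4.42, SE 0.58) and Asprv1 (4.37, SE 0.48). The lowest Tnf level of the 3 LPS animals was 9.50, against 4.27 as the highest of 56 untreated animals. The highest untreated levels of Tnf (4.27) and Cxcl2 (3.77) lay under the lowest array median of 4.53. No detection p was used, so these rises are against a level not shown to be above background, and their sizes and ranks depend on it. The untreated mean lay under that median for 7 of the 10 largest rises. No probe fell in limma at the adjusted threshold in the values as deposited, while 8 fell with quantile normalization, 1 with the chip as a block, 1 among the brighter probes alone and 14 when only the groups compared were fitted. Of the 944 probes with an unadjusted p under 0.05, 265 were lower.

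Of the 32 measured members of the cytokine and NF-kB list 12 rose at 0 h (24 when adjusted over the list alone) and none fell (camera adjusted p = 2.65e-66). Of 23 neutrophil genes 10 rose (12 when adjusted over the list alone, camera adjusted p = 1.67e-48), among them the receptors Il1r2 (4.28, SE 0.61) and Clec4d (3.82, SE 0.41). Glucocorticoid-responsive genes (4 of 18 rose, also 4 when adjusted over the list alone, camera adjusted p = 1.66e-12) included the mRNA decay factor Zfp36 (3.20, SE 0.29) and the phosphatase Dusp1 (1.40, SE 0.29). The heat shock list (2 of 12 rose, 4 when adjusted over the list alone, camera adjusted p = 1.99e-11) was led by the chaperones Hspa1a (3.82, SE 0.61) and Dnajb1 (1.48, SE 0.21). Hspa1a overlapped with untreated animals, at 10.94 to 12.01 after LPS against a highest untreated level of 11.93. The heat shock scores of the 3 LPS animals (10.14, 10.39 and 10.72) all lay under the highest score of untreated animals at 36 h (10.50, 10.66 and 10.95). These 4 lists were also called with an estimated correlation, with adjusted p of 0.00125, 2.08e-05, 0.0258 and 0.00125. With the chip as a block their mean shifts were 2.87 (SE 0.56), 1.92 (SE 0.40), 0.85 (SE 0.21) and 0.91 (SE 0.16), against 2.38, 1.88, 0.67 and 0.74 without it.

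A further 6 lists were called at 0 h, and each call was lost with an estimated correlation. The interferon list shifted up (2 of 31 rose, 4 when adjusted over the list alone, camera adjusted p = 6.13e-05, adjusted p = 0.46 with an estimated correlation), with rises of Cxcl10 (4.10, SE 0.95) and the transcription factor Irf1 (1.64, SE 0.28). No member passed in the other 5, although 1 alveolar type 2 gene fell when adjusted over the list alone. Smooth muscle (camera adjusted p = 0.0122) and ER stress genes (0.0259) shifted up, with adjusted p = 0.444 and adjusted p = 0.406 with an estimated correlation. Alveolar type 2 (0.00931), alveolar type 1 (0.012) and xenobiotic metabolism genes (0.0203) shifted down, with adjusted p = 0.406, 0.383 and 0.46 with an estimated correlation. The smooth muscle call was lost with the chip as a block (adjusted p = 0.314), and the ER stress list turned to a mean of -0.03 with array medians subtracted. Each of these 5 calls was also lost when 1 of the animals at 0 h was left out. For xenobiotic genes this was LPS replicate 1 (camera adjusted p = 0.35), for smooth muscle untreated replicate 2 (0.213).

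At 4 to 12 h the mean levels of chemokine, interferon and acute phase transcripts stood far above untreated means, although 2 of the 11 LPS animals, at 4 h, lay within the untreated range on the cytokine and acute phase lists. Over 11 LPS and 9 untreated animals, the T cell attracting chemokines Cxcl10 and Cxcl9 were higher by 9.64 (SE 0.53, adjusted p = 2.90e-26) and 8.29 (SE 0.47) log2 units. The antiviral gene Oasl1 rose by 7.28 (SE 0.37), the decoy receptor Il1r2 by 7.33 (SE 0.34), the acute phase protein Saa3 by 7.23 (SE 0.50), the neutrophil enzyme Mpo by 6.72 (SE 0.61) and the pattern recognition protein Ptx3 by 6.57 (SE 0.55). Cxcl2, Cxcl1 and Ubd completed the 10 largest rises, at 8.14 (SE 0.58), 7.66 (SE 0.57) and 6.69 (SE 0.50). In all 5332 probes rose and 5125 fell. The balance depended on the scaling, with 4748 and 6203 after quantile normalization and 4035 and 5577 with array medians subtracted (51% rises, then 43.4% and 42%). For 5 of the 10 largest rises (Cxcl2, Il1r2, Mpo, Ubd and Ptx3) the untreated mean lay under the lowest array median of 4.53, so their sizes and ranks depend on a level not shown to be above background. The count was 10378 without the 4 h groups, a setting added later.

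All 23 neutrophil genes rose at 4 to 12 h (camera adjusted p = 2.83e-23), including the granule gene Ngp (5.75, SE 0.50), which was also dim in many untreated animals. Of the interferon list 29 of 31 members rose (camera adjusted p = 9.02e-30), including Mx1 (6.14, SE 0.49), and 30 of 32 cytokine and NF-kB genes rose (8.42e-24), including Ccl2 (6.45, SE 0.52) and Ccl3 (6.18, SE 0.48). Acute phase genes (20 of 21 rose, 21 when adjusted over the list alone, 3.34e-17) included Orm1 (5.77, SE 0.47) and the metallothionein Mt2 (5.87, SE 0.42). Mt2 also stands on the glucocorticoid list (16 of 18 rose and 1 fell, 2 when adjusted over the list alone, 2.72e-10) with Fkbp5 (2.67, SE 0.18). Cell cycle genes rose in 21 of 27 cases (4.25e-09), with Top2a at 2.44 (SE 0.22) and Birc5 at 2.38 (SE 0.16). With an estimated correlation these lists kept their calls at adjusted p of 0.00424, 0.0258, 0.0292, 0.0396 and 0.0354, except that the cytokine list had adjusted p = 0.0674 with an estimated correlation. Within chips the LPS and untreated animals were often of other collection times, in this window and at 24 to 44 h, so these shifts mix time of day with LPS. In the 3 chips that held both arms the shift was positive in 3 of 3, at 3.08 to 4.35 for neutrophil, 2.70 to 4.05 for interferon and 2.46 to 4.49 for cytokine genes. It was 2.39 to 3.95 for acute phase, 1.59 to 1.91 for glucocorticoid and 0.84 to 1.77 for cell cycle genes.

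Hypoxia-responsive genes (8 of 16 rose and 2 fell, camera adjusted p = 0.019, adjusted p = 0.208 with an estimated correlation) included the glycolytic regulator Pfkfb3 (3.44, SE 0.45) and the vasodilator peptide gene Adm (3.23, SE 0.29). Oxidative phosphorylation genes rose in 14 of 22 cases (camera adjusted p = 0.0222, adjusted p = 0.46 with an estimated correlation), led by Cycs (1.33, SE 0.26). That call was lost with quantile normalization (adjusted p = 0.993) and with array medians subtracted (adjusted p = 0.168). Among the brighter probes alone the hypoxia (adjusted p = 0.0562) and oxidative phosphorylation calls (adjusted p = 0.0805) were lost, at mean shifts of 1.04 and 0.29 against 0.93 and 0.29. Within the 3 chips the shifts were 0.75 to 1.02 and 0.17 to 0.50.

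Vascular and stromal transcripts fell in the same window. Sox18 was lower by a log2 change of -4.33 (SE 0.32, adjusted p = 1.17e-19), and of 23 endothelial genes 16 fell and 4 rose (camera adjusted p = 9.24e-05, adjusted p = 0.175 with an estimated correlation). Calcrl and Ramp2, which together form an adrenomedullin receptor, changed by -3.63 (SE 0.34) and -2.48 (SE 0.22), and the angiopoietin receptor Tek by -3.06 (SE 0.21). Cholesterol synthesis genes fell in 9 of 13 cases (10 when adjusted over the list alone, camera adjusted p = 0.00321, adjusted p = 0.401 with an estimated correlation), led by Sc5d (-2.37, SE 0.29) and Dhcr7 (-1.82, SE 0.25). Of the fibroblast and matrix list 10 of 19 fell (11 when adjusted over the list alone) and 2 rose (camera adjusted p = 0.0135, adjusted p = 0.406 with an estimated correlation), with elastin, Eln, at -2.63 (SE 0.23). Among the brighter probes alone that call was lost (adjusted p = 0.0712), at a mean shift of -0.58 against -0.57. Shifts were negative in 3 of 3 chips, at -1.39 to -0.73, -1.09 to -0.52 and -0.72 to -0.39. The largest single falls were Tspan18 (-5.06, SE 0.43), Rflna (-4.86, SE 0.34), the Wnt receptor gene Fzd2 (-4.79, SE 0.44), Wscd1 (-4.78, SE 0.35), and Tppp (-4.40, SE 0.35). They were followed by Rbp7 (-4.29, SE 0.35), the noradrenaline transporter gene Slc6a2 (-4.20, SE 0.35), C1qtnf7 (-4.11, SE 0.43) and Sh3tc2 (-4.08, SE 0.38). For 6 of the 10 largest falls the LPS mean lay under the lowest array median, so the size of these falls depends on the background.

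Several lists not called at 4 to 12 h held members that moved both ways. Of the monocyte and interstitial macrophage list (adjusted p = 0.26) Plac8 and Fcgr1 rose by 2.98 (SE 0.15) and 2.97 (SE 0.27) while the fractalkine receptor Cx3cr1 changed by -2.96 (SE 0.37). Dendritic cell genes (0.171) included a rise of Ccl17 by 3.32 (SE 0.26) and a fall of the integrin gene Itgae (-2.31, SE 0.31). Coagulation genes rose in 10 of 16 cases (0.0533), with the fibrinogen chain Fgg at 4.38 (SE 0.55). Red cell genes rose in 3 of 7 cases (0.284), led by Slc4a1 (2.78, SE 0.45), and Aqp5, a water channel gene of alveolar type 1 cells (7 of 12 fell, 0.144), changed by -0.92 (SE 0.11). Of the heart muscle list 2 of 12 fell (0.982), Actc1 (-2.35, SE 0.84) and Myh7 (-0.76, SE 0.28), and of the fat list none of 7 passed (0.692). For heart muscle, club, ER stress and heat shock genes the median, the mean and the test did not share 1 sign. The same held for 8 lists at 0 h and 4 at 24 to 44 h (dendritic, monocyte, heat shock and fat), and none of these lists was called.

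**Figure D2:**
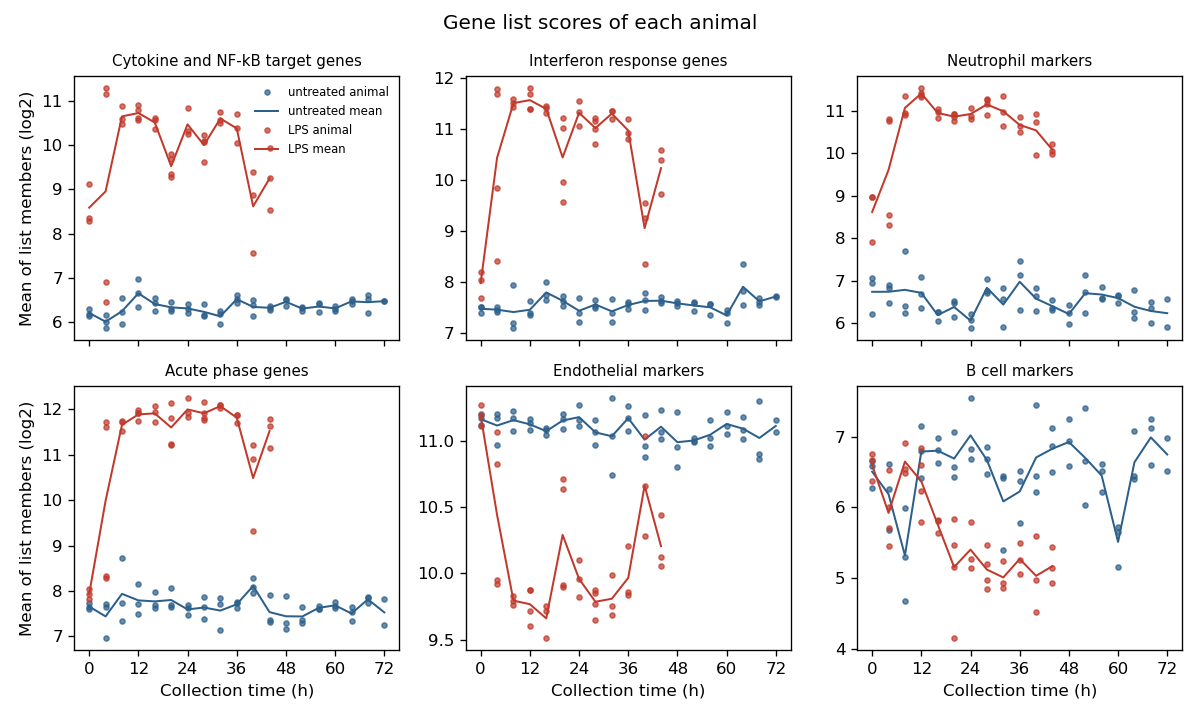
Mean log2 level of the members of 6 gene lists (cytokine and NF-kB, interferon, neutrophil, acute phase, endothelial, B cell) in each LPS and untreated animal against collection time in h; points are animals and lines are group means. The acute phase scores of the 3 LPS animals at 40 h were 9.32, 11.22 and 10.91, above the highest untreated score of 8.73.

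One to almost 2 days after injection, acute phase, chemokine and neutrophil granule transcripts remained high. Averaged over 24 to 44 h (19 LPS and 18 untreated animals), Saa3 was higher by 9.46 log2 units (SE 0.36, adjusted p = 3.77e-36), Cxcl10 by 9.02 (SE 0.38), Ngp by 8.95 (SE 0.37), Cxcl2 by 8.94 (SE 0.43), Cxcl9 by 8.61 (SE 0.34) and Il1r2 by 8.24 (SE 0.25). Cxcl1 (7.61, SE 0.42), the antimicrobial peptide gene Camp (7.11, SE 0.41), Mpo (6.82, SE 0.44) and the monocyte chemokine Ccl2 (6.76, SE 0.38) followed. For 5 of these 10 (Ngp, Cxcl2, Il1r2, Mpo and Ccl2) the untreated mean lay under the lowest array median of 4.53, so here too sizes and ranks depend on a level not shown to be above background. In this window 7355 probes rose and 6915 fell, 14270 in all, and without the 40 h groups, a setting added later, the count was 14130.

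All 23 neutrophil genes rose at 24 to 44 h (camera adjusted p = 2.11e-16, adjusted p = 0.0258 with an estimated correlation), as did 16 of 18 glucocorticoid-responsive genes, with 1 fall (1.37e-11, adjusted p = 0.0292 with an estimated correlation). The latter included Lcn2 (4.50, SE 0.16), which codes for an iron-sequestering protein of neutrophils and epithelium, the cell cycle inhibitor Cdkn1a (4.03, SE 0.13) and the metabolic kinase Pdk4 (3.78, SE 0.16). Interferon genes rose in 29 of 31 cases (2.68e-16, adjusted p = 0.133 with an estimated correlation). Cytokine and NF-kB genes rose in 31 of 32 cases (6.44e-16, adjusted p = 0.178 with an estimated correlation), with Il6 at 5.88 (SE 0.41). Acute phase genes rose in 20 of 21 (5.26e-14, adjusted p = 0.0561 with an estimated correlation). Cell cycle genes rose in 22 of 27 cases (23 when adjusted over the list alone, 6.57e-06, adjusted p = 0.133 with an estimated correlation), with Cdk1 at 2.06 (SE 0.16), 1 of whose 3 probes was called with the opposite sign. In 7 of 7 chips with both arms the shifts were positive, at 3.20 to 4.86 for neutrophil, 1.72 to 3.02 for glucocorticoid, 2.11 to 3.99 for interferon, 2.45 to 4.61 for cytokine, 2.78 to 4.57 for acute phase and 0.43 to 1.27 for cell cycle genes.

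The clock output list (10 of 17 rose, 1 fell, camera adjusted p = 0.00347, adjusted p = 0.153 with an estimated correlation) was led by Cdkn1a, Pdk4, Fkbp5 (3.37, SE 0.13) and the cold-inducible gene Rbm3 (2.26, SE 0.09), 2 of whose 3 probes were called with the opposite sign. Cdkn1a, Pdk4, Fkbp5, Tsc22d3 and Klf9 also stand on the glucocorticoid list, so the calls of these lists are not independent. Of the clock list 12 of 22 genes rose and 4 fell (13 and 5 when adjusted over the list alone, 0.012, adjusted p = 0.208 with an estimated correlation). The repressor Nfil3 rose by 3.73 (SE 0.17), the kinase Csnk1d by 2.54 (SE 0.09) and Arntl by 1.93 (SE 0.10), and Per3 changed by -2.16 (SE 0.27). Oxidative phosphorylation genes rose in 13 of 22 cases and fell in 1 (0.0207, adjusted p = 0.46 with an estimated correlation), with Cox5b at 0.70 (SE 0.04), and this call was lost with quantile normalization (adjusted p = 0.937). With the chip as a block, which keeps collection times matched, the mean shifts were 1.01 (SE 0.06) for clock outputs and 0.67 (SE 0.04) for the clock list, against 1.02 and 0.66 without it.

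The marker lists of B, ciliated, alveolar type 2, endothelial, smooth muscle and fibroblast cells were called downward at 24 to 44 h at the preset correlation, and each call was lost with an estimated correlation. Of 13 B cell genes 9 fell (camera adjusted p = 0.00321, adjusted p = 0.406 with an estimated correlation), among them Blk (-3.66, SE 0.25), Fcmr (-3.56, SE 0.15), Cd79a of the B cell receptor (-2.65, SE 0.19) and Cd22 (-1.65, SE 0.16). Ciliated cell genes fell in 10 of 14 cases (0.00234, adjusted p = 0.435 with an estimated correlation), with the axonemal gene Dnali1 at -2.57 (SE 0.25). Endothelial genes fell in 14 of 23 cases and rose in 4 (0.0122, adjusted p = 0.406 with an estimated correlation), with the apelin receptor Aplnr at -4.87 (SE 0.25) and Sox18 at -4.08 (SE 0.24). Smooth muscle genes fell in 9 of 10 cases (0.00393, adjusted p = 0.406 with an estimated correlation), with Lmod1 at -2.32 (SE 0.25). Alveolar type 2 genes fell in 10 of 16 cases and rose in 3 (0.0207, adjusted p = 0.44 with an estimated correlation), with Etv5 at -2.31 (SE 0.16) and Fasn at -1.54 (SE 0.24). Fibroblast and matrix genes fell in 12 of 19 cases and rose in 4 (0.0283, adjusted p = 0.444 with an estimated correlation), with Mfap5 at -2.87 (SE 0.19) and the collagen crosslinker Lox at 2.02 (SE 0.09).

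Genes of cholesterol synthesis and xenobiotic metabolism were lower as well. Cholesterol synthesis genes fell in 12 of 13 cases (camera adjusted p = 1.84e-04, adjusted p = 0.208 with an estimated correlation), with Sc5d at -3.37 (SE 0.21) and Fdps at -1.39 (SE 0.08). Xenobiotic metabolism genes fell in 13 of 19 cases and rose in 3 (0.00321, adjusted p = 0.406 with an estimated correlation), with Cyp2e1 at -2.31 (SE 0.37) and Ephx1 at -1.98 (SE 0.09). All 8 lists called downward were negative in 7 of 7 chips, at -1.96 to -0.55 for B cell, -3.24 to -0.56 for ciliated, -1.25 to -0.57 for endothelial and -2.17 to -0.53 for smooth muscle genes. The ranges were -0.90 to -0.22 for alveolar type 2, -1.27 to -0.30 for fibroblast, -2.30 to -0.60 for cholesterol and -1.62 to -0.20 for xenobiotic genes. Ciliated and smooth muscle scores went with the heart muscle score. In chip 14, which had the lowest values, the shifts were -3.24 for ciliated, -2.17 for smooth muscle and -5.57 for heart muscle genes. With the heart muscle score as a covariate, a setting added later, the ciliated shift went from -1.32 (SE 0.16) to -1.17 (SE 0.12) and that of smooth muscle from -1.29 (SE 0.15) to -1.18 (SE 0.13), and both calls were kept. Club cell genes, not called in either fit, went from -0.81 (SE 0.27) to -0.49 (SE 0.17). Among the brighter probes alone the fibroblast, alveolar type 2, endothelial and smooth muscle calls were lost (adjusted p = 0.201, 0.174, 0.172 and 0.0688), although the mean shifts were -0.64, -0.63, -0.998 and -1.29 against -0.62, -0.63, -1.03 and -1.29 over all probes. The largest single falls were Stmn2 (-5.68, SE 0.27), Fzd2 (-5.37, SE 0.32), Slc7a10 (-5.09, SE 0.28), Ushbp1 (-5.05, SE 0.27), Rflna (-4.92, SE 0.25), Aplnr, Tril (-4.86, SE 0.22), Magix (-4.85, SE 0.26), Rbp7 (-4.81, SE 0.26) and Pcdha6 (-4.79, SE 0.25), and for 7 of these 10 the LPS mean lay under the lowest array median.

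Among the 13 lists not called at 24 to 44 h, T and NK cell genes fell in 10 of 19 cases and rose in 3 (adjusted p = 0.0607), with Klrd1 at -3.17 (SE 0.18) and Cd3g at -3.17 (SE 0.16). Of the monocyte list (0.44) Cx3cr1 changed by -4.20 (SE 0.27), and of the dendritic list (0.958) Cd209a changed by -3.31 (SE 0.20). Alveolar macrophage genes (0.405) included rises of the scavenger receptor Marco (2.39, SE 0.22) and of Chil3 (0.95, SE 0.08), and a fall of Pparg (-1.15, SE 0.09). Vegfa, on the alveolar type 1 list (0.0992), changed by -1.65 (SE 0.08), and the club cell enzyme Cyp2f2 (list 0.221) by -1.78 (SE 0.14). Of the heat shock list (0.983) Hspa1a, which had risen at 0 h, was lower by a log2 change of -2.71 (SE 0.25) and Hspb1 was higher by 1.76 (SE 0.10). Among ER stress genes (0.376) Atf4 rose by 1.71 (SE 0.15), among hypoxia genes (0.284) Adm rose by 4.16 (SE 0.21), and among coagulation genes (0.212) Fgg rose by 4.46 (SE 0.41). Of the red cell list (0.673) Slc4a1 rose by 2.45 (SE 0.33), of the heart list (0.719) Actc1 changed by -3.69 (SE 0.62), and of the fat list (0.949) Lipe alone of 7 rose, by 0.43 (SE 0.17), and none did when adjusted over the list alone.

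Effects differed between the windows for 6563 probes, of which 2770 were higher and 3793 lower at 24 to 44 h than at 4 to 12 h. The B cell list effect was lower by -1.63 log2 units (SE 0.23) in the later window, with Blk at -3.24 (SE 0.42, adjusted p = 4.15e-09), the ciliated list effect by -1.16 (SE 0.27), and the interferon effect by -0.62 (SE 0.25). In settings added later the interferon difference was -0.28 (SE 0.26) without the 40 h groups, -0.43 (SE 0.28) without the 8 h groups and -0.99 (SE 0.29) without the 4 h groups, so it rested on single times. The B cell effect was 1.33 (SE 0.33) at 8 h, against -0.26 (SE 0.31) at 4 h and -0.42 (SE 0.31) at 12 h, and without the 8 h groups its difference was -1.08 (SE 0.26). The ciliated difference was -0.98 to -1.33 without the 4, 8 or 40 h groups. Ifng and the lymphocyte chemokine Xcl1, chosen with Dio2 and Ngp from the largest differences after their values were seen, went down by -3.09 (SE 0.62) and -5.03 (SE 0.59). The thyroid hormone activating enzyme Dio2 went up by 3.34 (SE 0.39) and Ngp by 3.21 (SE 0.62). At 40 h 4954 probes differed from the mean of 36 and 44 h, and at 20 h 3774 differed from the mean of 16 and 24 h. The LPS animals at 20 h were divided. Replicates 1 and 4 had interferon scores of 9.96 and 9.57, endothelial scores of 10.64 and 10.71 and monocyte scores of 9.47 and 9.74. Replicates 2 and 3 had 11.01 and 11.21, 9.90 and 9.91, and 8.41 and 8.17. The interferon effect at 40 h was lower by -1.58 (SE 0.44), the clock list effect by -1.02 (SE 0.12) and the endothelial effect higher by 0.71 (SE 0.21), whereas the neutrophil effect differed by 0.28 (SE 0.44). Parp9, an interferon target also chosen after its value was seen, differed by -5.86 (SE 0.92, adjusted p = 1.74e-06) at 40 h.

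In untreated lungs the transcripts of the core clock swung with a period close to a day. Arntl, the positive limb transcription factor of the clock, had an amplitude of 2.07 log2 units (SE 0.10) with a peak at 14.4 h after the start of collection. The repressor Nr1d1 had 2.23 (SE 0.10, peak 23.4 h) and the output activator Dbp 2.59 (SE 0.11, peak 1.2 h). Per3 (1.79, SE 0.14, 3.5 h), Npas2 (1.51, SE 0.14, 14.7 h), Nr1d2 (peak 1.6 h), Nfil3 (1.28, SE 0.07, 13.3 h), Per2 (1.11, SE 0.09, 5.5 h), Tef (0.86, SE 0.07, 3.2 h) and Per1 (0.49, SE 0.08, 3.2 h) were also rhythmic. So were Clock (0.48, 14.5 h; 1 of its 3 probes differed in sign and was called after LPS), Ciart (0.44, 0.5 h), Cry2 (0.36, 3.9 h), Bhlhe40 (0.33, 2 h), Rora (0.15, 5.5 h) and Csnk1d (0.13, 2.4 h). In all 16 of 22 clock genes passed, also 16 when adjusted over the list alone, and Cry1, Rorb, Hlf, Bhlhe41, Csnk1e and Timeless did not (adjusted p of 0.279 to 0.917). The period that best fitted the 16 genes was 25.2 h (SE 0.076, 95% bootstrap interval 25.1 to 25.4 h).

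Over 0 to 72 h 2331 probes were rhythmic in the 56 untreated animals, with a median amplitude of 0.207, and 247 exceeded 0.5. With array medians subtracted the count was 775. Peaks gathered at 12 to 16 h (33.5%) and 16 to 20 h (23.9%). The largest amplitudes outside the clock list were those of the neutrophil granule genes Camp (2.82, SE 0.37, peak 7.2 h) and Ngp (2.17, SE 0.28, 7.4 h). Untreated levels ran from -1.74 to 9.28 for Camp (median 4.66) and from 1.05 to 9.35 for Ngp (median 4.09), around or under the array medians of 4.53 to 5.43 in many animals. The amplitudes and ranks of these 2 genes therefore depend on levels not shown to be above background. They were followed by Spon2 (2.06, SE 0.10, 15.9 h), Fam124b (1.48, SE 0.15), the muscle gene Tcap (1.37, SE 0.35), Adamts4 (1.37, SE 0.17), Adm (1.32, SE 0.12), Ikzf4 (1.22, SE 0.11), the vasopressin receptor gene Avpr1a (1.16, SE 0.11) and Eln (1.15, SE 0.08, 15.9 h). By list, 12 of 17 ER stress, 11 of 18 glucocorticoid, 10 of 17 clock output, 9 of 13 cholesterol synthesis, 9 of 13 B cell, 11 of 19 xenobiotic and 8 of 12 heat shock genes were rhythmic. These were 12, 15, 12, 10, 11, 14 and 9 when adjusted over the list alone. None of 22 oxidative phosphorylation, 12 heart muscle, 7 fat or 15 alveolar macrophage genes was.

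After LPS the fitted 24 h amplitude was smaller for most clock genes that were rhythmic in untreated lungs. Each animal was collected at 1 time, so amplitudes describe the mean course over animals. Whether the clock within an animal or a cell swung less was not tested. The median ratio of LPS to untreated amplitude over the 13 clock genes rhythmic in untreated lungs at 0 to 44 h was -1.46 log2 units (SE 0.12, 95% bootstrap interval -1.69 to -1.20), a ratio of 0.364 (permutation p = 6.00e-05, two-sided, 100000 permutations). Arntl went from an amplitude of 2.06 (SE 0.11) to 0.33 (SE 0.20, adjusted p of the difference 3.92e-07), with a mean level of 10.32 (SD 0.10, n = 3) in LPS and 6.08 (SD 0.48, n = 3) in untreated lungs at 24 h. Npas2 went from 1.79 to 0.14 (3.92e-06), Nr1d2 from 1.55 to 0.32 (1.67e-09), and Nr1d1 from 2.27 to 0.83 (1.33e-05). Dbp went from 2.65 to 0.78 (2.46e-07), Per2 from 1.22 to 0.37 (0.00388), Tef from 0.90 to 0.30 (0.00293), Per3 from 1.79 to 0.88 (0.00356) and Clock from 0.49 to 0.19 (7.65e-09). The difference did not pass for Nfil3 (1.21 and 0.99, adjusted p = 0.226), Per1 (0.59 and 0.34, 0.173), Cry2 (0.46 and 0.55, 0.22) or Ciart (0.51 and 0.62, 0.47). Genes chosen for their rhythm in untreated lungs lean towards a ratio below 1. The permutations kept these 13 genes fixed, so their p does not cover this choice. Over the 15 genes rhythmic in either arm, a setting added later, the median was -1.38, and over all 22, also added later, it was -0.17. The fitted amplitude after LPS was the larger in 10 of 22, but the wave difference passed for none of these, and 8 of them had no called rhythm in untreated lungs at 0 to 44 h. Of these 8, Timeless (0.05, SE 0.06 in untreated and 0.59, SE 0.16 in LPS lungs, adjusted p of the difference 0.067) and Csnk1d (0.11, SE 0.03 and 0.69, SE 0.20, 0.0648) were rhythmic after LPS. Of 22 clock genes 9 differed in their wave (12 when adjusted over the list alone) and 8 were rhythmic after LPS (15 when adjusted over the list alone). At 24 h Arntl was higher by 4.24 (SE 0.24) and Dbp lower by a log2 change of -3.45 (SE 0.34), and at 36 h Nr1d1 was higher by 4.52 (SE 0.30).

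**Figure D3:**
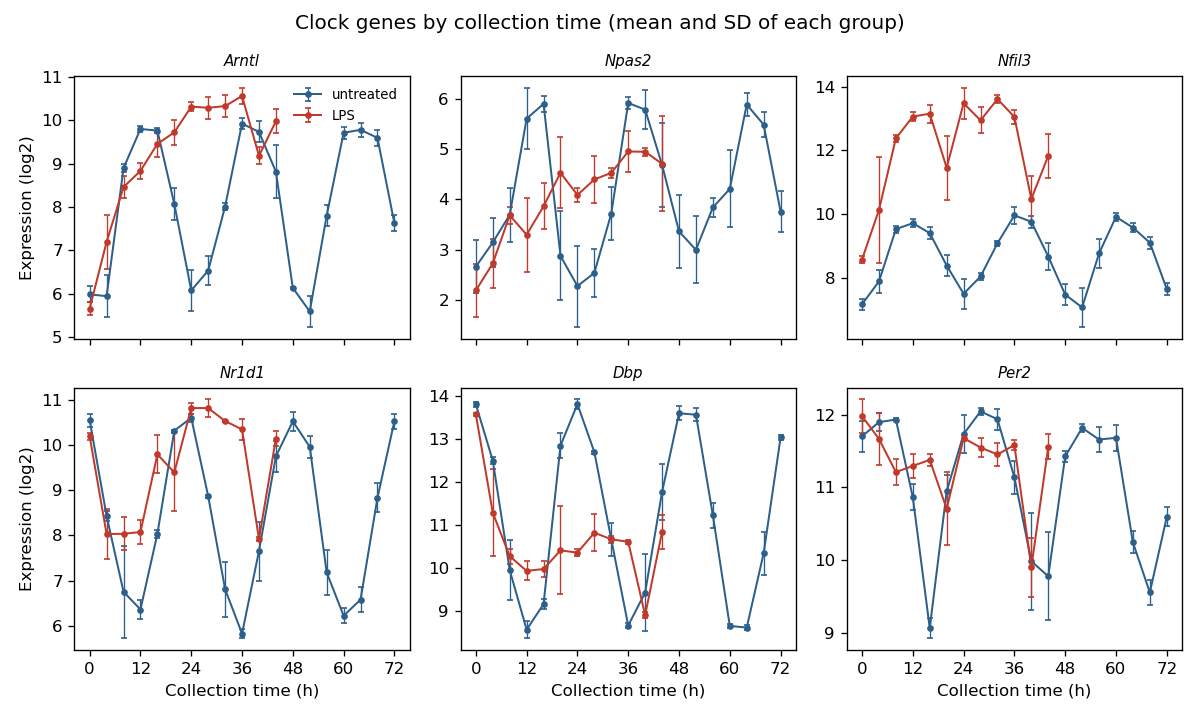
Mean log2 level with SD of the clock genes Arntl, Npas2, Nfil3, Nr1d1, Dbp and Per2 against collection time in h in LPS (0 to 44 h) and untreated (0 to 72 h) lungs, 2 to 4 animals per point. The fitted 24 h amplitude of Arntl over 0 to 44 h was 2.06 in untreated lungs and 0.33 after LPS.

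Other transcripts followed a 24 h wave after LPS. Over 0 to 44 h 4027 probes did so in LPS lungs (median amplitude 0.477) and 922 in untreated lungs (0.294). The largest amplitudes after LPS were those of Ifng (2.39, SE 0.52, peak 10.7 h), the basophil proteases Prss34 (2.06, SE 0.46) and Mcpt8 (2.06, SE 0.42), and Il17f (2.00, SE 0.56). Next came Cxcl10 (1.97, SE 0.54), Sox18 (1.92, SE 0.45, 21.4 h), Parp9 (1.87, SE 0.55), Mpo (1.86, SE 0.51), Islr2 (1.84, SE 0.49) and Ambp (1.83, SE 0.38). Several also had some of the largest differences in LPS effect at 20 h against 16 and 24 h. These were Ifng (-4.51), Il17f (-4.52), Prss34 (-3.74), Parp9 (-5.08), Mpo (-3.77) and Sox18 (3.60), but not Mcpt8, Cxcl10, Islr2 or Ambp. Their waves may thus partly reflect the 20 h group, whose LPS animals were divided. A wave that also held in the second cycle was found for 3076 probes after LPS and 755 in untreated lungs. These counts were 686 and 753 with no variance trend, 1287 and 981 without the 20 and 40 h groups, and 1055 and 800 without the arrays of low median, the last 2 settings added later. Among the recurrent waves after LPS were Sh3tc2 (1.72, SE 0.45), Mx1 (1.64, SE 0.48), the eosinophil granule gene Prg2 (1.63, SE 0.43) and Stmnd1 (1.58, SE 0.39). Peaks after LPS gathered at 16 to 20 h (44%) and 8 to 12 h (21.5%). By list, 18 of 27 cell cycle genes were rhythmic after LPS (19 when adjusted over the list alone) and 0 of 27 in untreated lungs over 0 to 44 h (2 when adjusted over the list alone). Only 8 of 27 were recurrent after LPS, and the wave itself differed for 8 (13 when adjusted over the list alone).

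The count after LPS depended on the fitted period, the trend term and the variance model. With no trend term it was 1432 against 1431 in untreated lungs. It was 8493 at 20 h and 827 at 27 h, where untreated lungs gave 882, and without a variance trend it was 897 against 1153 in untreated lungs. Without the 20 and 40 h groups it was 2566 against 1400, and without the 11 arrays of lowest median 2068 against 972, both settings added later. Without the 20 and 40 h groups a period of 25 h gave 384 against 1329, and 26 h gave 490 against 1189. With the chip as a block the count was 5583 against 255.

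The wave itself differed between arms for 1718 probes. The count was 495 with the chip as a block, 688 with array medians subtracted and 449 with no variance trend. Outside the clock list the smallest p belonged to the Ras-like gene Rasl11a (amplitude 0.93 in untreated and 0.26 in LPS lungs, adjusted p = 1.61e-09), Dtx4 (0.70 and 0.34, 2.11e-07) and Eln (1.19 and 1.03, 7.12e-07), whose peak lay at 15.1 h in untreated and 21.4 h in LPS lungs. Slc46a3 (0.45 and 0.29), Spon2 (2.19 and 0.52) and Fkbp11 (0.34 and 0.24) had the smaller amplitude after LPS. Dkk3 (0.21 and 0.54; 1 of its 3 probes was called with the opposite sign), Ldb2 (0.07 and 1.08), Slc25a38 (0.14 and 0.36) and St3gal3 (0.04 and 0.73) had the larger amplitude after LPS. Probes rhythmic in both arms numbered 293, against 144.5 expected for independent lists (Fisher's exact test, two-sided p = 1.76e-35). That test takes probes as independent, and probes hard to call in both arms can also raise the overlap. Of the 293, 147 peaked within 4 h of each other in both arms. No chance value was computed for this, and peaks of both arms were frequent at 16 to 20 h (25.9% in untreated, 44% in LPS lungs). Leaving out LPS 32 h replicate 2, LPS 0 h replicate 2, LPS 20 h replicate 1 or LPS 24 h replicate 1 gave 1098, 1113, 1131 or 2881 differing probes. Without LPS 32 h replicate 2 the count of recurrent waves after LPS was 2013.

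**Figure D4:**
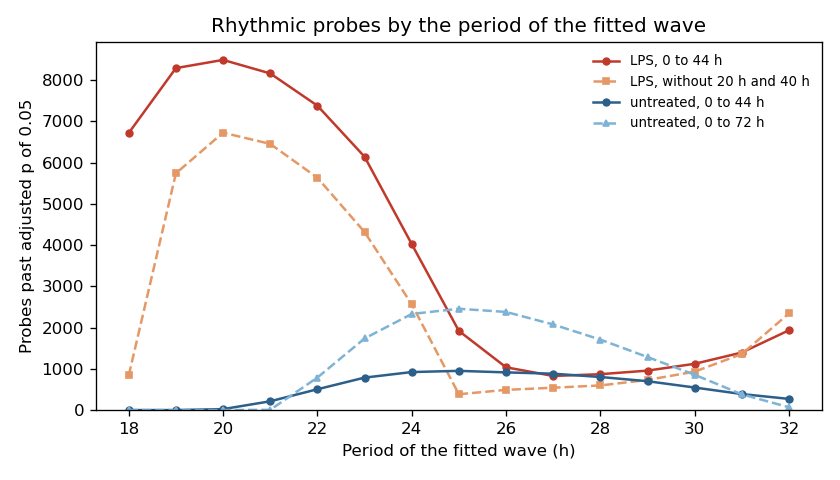
Number of probes with a wave at an adjusted p under 0.05 against the fitted period in h, for untreated (0 to 72 h and 0 to 44 h) and LPS lungs (with and without the 20 and 40 h groups). Untreated counts were highest at 25 h (2457 and 951) and LPS counts at 20 h (8493 and 6728).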

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

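Of the tests of an explanation in this part, those of time of day at 40 h and of more neutrophils at 0 h had their bounds fixed before the value was seen, and all others, the comparisons with regrouped animals, those between times and the settings without the 20 and 40 h groups, without the arrays of low median or with periods other than 23 and 25 h among them, were chosen after the result was seen; the rhythm difference, the clock amplitude and the fits with the chip as a block, no trend term or no variance trend were planned.

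In 4 groups of 4, 30 list scores and the array median, 124 values in all, were tested for an animal far from the other 3. Of these 8 stood out, all of them list scores, where chance gives about 1 in 20 (5%). A share of 8 in 124 is close to that, so the values below may stand out by chance alone. At 4 h after LPS, replicate 4 had a heart muscle score of 8.81, against 3.98 to 4.14 in the others. At 12 h replicate 1 had low alveolar type 1 (10.43, others 10.75 to 10.79) and heat shock scores (9.54, others 9.84 to 9.89). At 20 h replicate 2 had a club cell score of 11.30 (others 8.82 to 9.21) and also the highest level of the heart gene Myh6 after LPS (12.95). At 28 h replicate 3 had a high club cell score (11.26, others 8.28 to 8.69) and low cell cycle (6.16, others 6.56 to 6.64) and red cell scores (8.16, others 8.62 to 8.69), and replicate 4 an alveolar macrophage score of 6.76 (others 6.66 to 6.67). Groups of 3 were not tested.

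Tests of a difference between groups found 1718 probes whose 24 h wave differed between LPS and untreated lungs and a clock amplitude ratio of -1.46 log2 units. The LPS effect differed between 24 to 44 h and 4 to 12 h for 6563 probes, between 40 h and the mean of 36 and 44 h for 4954, and between 20 h and the mean of 16 and 24 h for 3774.

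At 40 h fewer probes differed (3835) than at 36 h (9425) or 44 h (8206), and Sox18, Arntl and Nfil3 did not pass. Untreated animals carrying an LPS label were argued against by acute phase scores of 9.32, 11.22 and 10.91, all 3 above the highest untreated score of 8.73. Differences between chips were argued against by a count of 3890 with the chip as a block. For time of day, the interferon effect was higher by 2.17 log2 units (SE 0.51) at 16 h than at 40 h, the same phase of a 24 h day. By the bound fixed beforehand this value argued against time of day. The 16 h and 40 h groups also differ in the time since injection, so this comparison cannot decide the question. Another course in the animals collected at 40 h may remain, not milder in every list, since the interferon effect lay -1.58 (SE 0.44) from its neighbours while the monocyte effect was higher by 1.54 (SE 0.25) and the monocyte scores (10.21, 9.82 and 9.70) lay above the highest untreated score of 8.97, and a difference in dose received was not tested.

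At 0 h 139 probes were already higher, led by Tnf. A single wrong LPS label was argued against by the lowest count without 1 LPS animal, 85 without replicate 3. More blood in the samples was argued against by the red cell, B cell and T and NK cell lists, 0 of 3 of which lay above 0 by more than 2 standard errors. For more neutrophils, the median of 9 granule and cytosol genes was 0.65 (SE of the mean 0.51), and by the bound as first written this value argued against the explanation. It was set to undecided after the values were seen, because S100a8 (2.40), S100a9 (2.79) and Mmp9 (2.85) rose while Camp (0.27), Ngp (0.63), Ltf (0.39), Mmp8 (0.79), Mpo (0.36) and Elane (0.65) did not pass. The other 14 neutrophil genes had a median of 1.92, and the interval between injection and collection of these lungs, which could also account for the 139 probes, is not given and was not tested.

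More probes followed a 24 h wave after LPS (4027) than in untreated lungs over 0 to 44 h (922). A response that falls and returns with another spacing may contribute, since of the periods tried the most probes after LPS were found at 20 h (8493), against 25 h in untreated lungs. The smaller response at 20 and 40 h as the whole source was argued against in the 24 h fit alone, by 2566 probes against 1400 without those groups, since at 25 h the same setting gave 384 against 1329, and arrays of low median were argued against by 2068 probes against 972 without them. With the chip as a block the difference was larger (5583 against 255), with no trend term there was none (1432 against 1431), and with no variance trend (897 against 1153) or a period of 27 h (827 against 882) the order turned. A larger number of daily rhythms after LPS was therefore not established.

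Regroupings of the same animals gave the following. With 3 against 3 animals only 10 splits exist, too few for a share under 0.05, and the real split was the 1 with the most probes at 0 h (139, highest other 0), 8 h (8475, 7), 16 h (8784, 0), 24 h (9625, 1), 32 h (10343, 1320), 36 h (9425, 385), 40 h (3835, 443) and 44 h (8206, 1612). At 4 h 6 of 35 splits gave as many probes as the real 3264 (highest other 4673), so chance was not excluded. The real split was the 1 of 35 with the most probes at 12 h (9333, highest other 7010), 20 h (6764, 6081) and 28 h (10725, 9578). That share is under 0.05, but it is the smallest that 35 splits can give and was not adjusted over the times. At 20 h and 28 h another split came close, so there the count does not set the real labels well apart.

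Chance was excluded with 1 of 100 splits as large for 4 to 12 h (10457, highest other 3906), 24 to 44 h (14270, 10597), rhythms in untreated lungs over 0 to 72 h (2331, 34) and 0 to 44 h (922, 36), and rhythms after LPS (4027, 3). It was also excluded for recurrent rhythms in untreated (755, 24) and LPS lungs (3076, 3). For rhythms the splits shuffled collection times within an arm, so they stand for no change over time at all. After LPS a time course of another shape could exceed them as well as a daily wave. For list shifts the real labels gave the most calls (38, highest other 35), with 1 of 100 splits as large. The other splits of the lists had a median of 20 calls, so camera also called many lists with wrong labels. Neither the count of 38 nor the call of a single list is set well apart from chance by this comparison. For the rhythm difference 4 of 100 splits gave as many probes as the real 1718, and the highest of the others was 7417. These splits mix LPS and untreated animals in shares that vary over time, so the LPS effect itself can make waves differ. They are therefore no clean test of the wave difference, and what gave 7417 was not tested.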

How the results depend on the processing

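Settings without the 4 h, 8 h or 40 h groups, without the 20 and 40 h groups, without arrays of low median, without exchanged list members, with the heart muscle score as a covariate, with other clock genes and with periods of 22 h and 27 h were chosen after seeing the data; the other settings were fixed before the data were examined. No paired analysis was possible because replicate numbers are names given in order of deposition and link no LPS animal to an untreated one. The values numbered 24385, from 29 settings and from leaving out each of the 96 animals in turn. Among them no test with a call turned to the opposite direction. At 0 h the mean of the called ER stress list changed from 0.14 to -0.03 with array medians subtracted (camera adjusted p = 0.18). Every gene shifts with the scaling in that setting. Unless a cause follows from the setting itself, the cause was not tested.

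Of the planned values, 2020 of 2072 for LPS effects on named genes kept direction and side of the threshold (8 of 270 calls were lost in at least 1 setting), 1165 of 1284 for named rhythms (26 of 80 lost) and 518 of 627 for lists (27 of 38 lost). With 1 animal left out these were 8913 of 9068 (11 lost), 6241 of 6456 (11 lost) and 1835 of 1890 (5 lost). In added settings they were 559 of 578 (7 of 251 lost), 459 of 524 (25 of 80 lost) and 289 of 297 (0 of 38 lost). For list differences between the windows 7 of 9 values did so (1 of 3 lost, interferon).

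With array medians subtracted the rhythm counts were 775 (untreated, 0 to 72 h), 258 (untreated, 0 to 44 h), 2312 (LPS), 688 (difference), 242 (recurrent, untreated) and 1846 (recurrent, LPS). With the chip as a block they were 255 (untreated, 0 to 44 h), 495 (difference) and 233 (recurrent, untreated), while those after LPS rose to 5583 and 4094 (recurrent). The brighter probes alone gave a difference of 2805. With no variance trend the counts were 897 (LPS), 449 (difference) and 686 (recurrent, LPS).

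A 2-fold minimum, which removes smaller changes by construction, gave 1688 probes at 4 h, 5550 at 8 h, 5968 at 12 h, 5711 at 16 h, 3939 at 20 h, 2127 at 40 h, 5207 at 44 h, 4176 at 4 to 12 h and 5977 at 24 to 44 h. Fitting only the groups compared, which takes the spread from those groups alone, gave 251 at 0 h (237 higher, 14 lower), 12 at 4 h and 2052 at 20 h. The LPS animals at 4 h and at 20 h were divided, so the spread pooled over all groups may understate theirs.

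With no trend term the wave counts were 1431 (untreated, 0 to 44 h), 1432 (LPS) and 622 (difference). A period of 23 h gave 6145 (LPS) and 3561 (difference), and 25 h gave 1920 and 545. The window of 12 to 44 h gave 300 (untreated), 6883 (LPS) and 3850 (difference). A peak tolerance of 2 h gave 1944 recurrent waves after LPS, and the window of 24 to 72 h a clock period of 25.6 h. In the added settings 22 h gave 788 (untreated, 0 to 72 h), 505 (untreated, 0 to 44 h), 7383 (LPS) and 4780 (difference), and 27 h gave 827 (LPS) and 294 (difference). Without the 20 and 40 h groups the counts were 1400 (untreated, 0 to 44 h), 2566 (LPS) and 1287 (recurrent, LPS), and the clock amplitude ratio was -1.79 log2 units, or -1.64 without the 40 h groups alone. The ratio was -0.17 over all 22 measured clock genes, which include those without a called rhythm in untreated lungs, and -1.38 over the 15 rhythmic in either arm. Without the arrays of low median the counts were 2068 (LPS) and 1055 (recurrent, LPS).

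With an estimated correlation 11 lists were called, 4 at 0 h, 5 at 4 to 12 h and 2 at 24 to 44 h, all upward. With fry, which asks whether a list moves at all and not whether it moves more than other genes, 4, 23 and 26 were called.

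Leaving out 1 animal gave ranges of 85 to 130 probes at 0 h (85 without LPS replicate 3), 1330 to 4583 at 4 h (1330 without LPS replicate 4, 1332 without LPS replicate 3, 1978 without untreated replicate 1) and 2415 to 4180 at 40 h (2415 without LPS replicate 3). It gave 2013 to 3899 recurrent waves after LPS (2013 without LPS 32 h replicate 2) and a rhythm difference of 1098 to 2881 (1098 without LPS 32 h replicate 2, 1113 without LPS 0 h replicate 2, 1131 without LPS 20 h replicate 1, 2881 without LPS 24 h replicate 1). The clock period was 25.2 to 25.3 h and the clock amplitude ratio -1.56 to -1.36. Dim probes limit what can be called, with a median standard deviation between animals of 0.597 over all probes and 0.292 over the brighter probes.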

Other observations

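All tests in this part, those of correlation and that of collection time, were chosen after the result was seen. The granule gene test was first planned over all 56 untreated animals, where it came out below its bound. The values then showed a gap, and the test was replaced by tests on each side of it. Whether the gap parts separate clusters was not tested.

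The 14 arrays of control RNA, which the labels put in no group, correlated at 0.783 to 0.792 with the mean of untreated lungs and had a median mutual correlation of 0.984 (lowest 0.974). Their median levels were 14.41 for Sftpc (untreated lungs 15.38), 10.64 for S100a8 (12.39), 9.03 for Saa3 (6.56), 8.66 for Isg15 (8.93), 7.53 for Arntl (8.12) and 1.69 for Alb (2.03).

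Untreated 8 h replicate 1 had the highest untreated levels of Saa3 (12.88), Lcn2 (14.19), Camp (9.28) and Ngp (9.35). Levels of the heart gene Myh6 ran from 2.38 to 12.48 in untreated and 2.44 to 12.95 in LPS lungs, and those of the fat gene Adipoq from 1.60 to 11.37 and 2.24 to 10.45.

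Heart muscle carried along in dissection is a candidate explanation for the spread of Myh6. Its levels had a gap between 5.32 and 5.96, with 51 animals above it (21 LPS, 30 untreated). Among these Myh6 and Tnni3 had a Pearson r of 0.936 (permutation p = 1.00e-05, two-sided, the smallest that 100000 permutations can give, adjusted over 4 relations 4.00e-05) and a Spearman rho of 0.938 (permutation p = 1.00e-05), with r 0.929 without the 2 farthest animals and 0.948 within chips. Among the 45 animals below the gap r was -0.0489 (permutation p = 0.757, adjusted 0.757) and rho 0.0486 (permutation p = 0.752).

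Numbers of granule-rich cells could differ between untreated lungs, but this stayed undecided. Over the 25 animals above the gap in the first set of granule genes (6.37 to 6.94) the sets had r 0.619 (permutation p = 9.30e-04, adjusted 0.00186) and rho 0.543 (permutation p = 0.0058), with r 0.445 without the 2 farthest animals and 0.515 within chips. Over the 31 animals below it r was -0.201 (p = 0.279, adjusted 0.372, permutation test) and rho -0.211 (permutation p = 0.253). The side of the gap went with the time of day (permutation p = 1.00e-05 of a chi-squared statistic, the smallest that 100000 permutations can give). The first set holds Camp and Ngp, which already had the largest 24 h amplitudes outside the clock list in the same animals. This test therefore restates that rhythm and adds no separate support. Of 9 animals each, 8 lay above the gap at 4 h, 8 at 8 h, 6 at 12 h, 1 at 16 h and 0 at 20 h, and at 0 h 2 of 11 did, counting each 24 h from the start of collection. Time of day and cell number can therefore not be told apart across the gap.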
